A study of Rattus norvegicus with 8 samples.

How the data were processed

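Total RNA of islets from 4 P10 and 4 adult Sprague Dawley rat samples was labelled with cyanine 3 and hybridised to Agilent rat miRNA arrays, per the labels. The deposited scanner files hold intensity values extracted with Agilent Feature Extraction 10.7.3.1, per the file headers, in which the processed signal is already background-subtracted and can be negative. The authors' value table holds 1 log2 value per miRNA and array, for 311 miRNAs. How it was made is not given in the sources used here. From the values, its rows were the 311 miRNAs that the scanner software detected on at least 1 array, its 8 columns shared 1 set of sorted values (tolerance 0.01), as after quantile normalization, every column had a median of 6.54, and the order of each column matched that array's total gene signal (Spearman correlation 1), so scale and direction are settled and no centring by miRNA was seen.

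The array held 13540 non-control features for 1644 probes and 677 miRNAs. Features flagged as population or non-uniformity outliers (2.34% to 3.65% per array) were left out, no non-control feature was saturated, and the remaining features of a probe were averaged. Each array was divided by the 75th percentile over the 278 probes well above background on all 8 arrays. Values were then raised to 1 common floor (the median over arrays of the 1st percentile of probes well above background, -5.51 on the log2 scale), and log2 was taken. A probe counted as well above background where the majority of its used features carried that call. Each miRNA was represented by its probe with the highest mean. Other probes of called miRNAs were compared where they were well above background on at least 4 of 8 arrays. They went the same way in 99 of 99 cases, with a median gap of 0.11 and 5 gaps above 1, for miR-17-5p, miR-181d, miR-129-1*, miR-129-2* and miR-344a-3p. miRNAs well above background on at least 4 of 8 arrays were tested, 238 in all.

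The ages were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, adult minus P10, no block), with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of arrays limits the precision. Where a miRNA was not well above background on any array of 1 age, the fold is a bound, the bright age's mean against the mean of, per array, the higher of the lowest signal well above background and the miRNA's own. Array-level values were tested with exact permutation tests. A set of 23 miRNA lists was fixed before the data were examined, and the 16 with at least 3 tested members were tested with camera at a preset correlation of 0.01. Of these 5 passed, and none passed with an estimated correlation. fry, which asks whether a list's members move on balance in 1 direction, called 10, and its mixed test 11.

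The rule for named miRNAs, also fixed before the data were examined, took the 10 largest differences each way among those called, above background on all 8 arrays and without overlap of the ages. It added up to 5 each way that were above background in 1 age only, a fixed set of islet and cell type miRNAs, and up to 4 examples per list (in a list with none past the threshold, its 2 largest differences). It named 73. miR-148a, in the fixed set, had no probe on this array. miRNA names are those of the array, and 235 of 238 tested were matched to a RefSeq miRNA gene of the assembly GRCr8. The array's design uses the rn4 build, so no coordinates are given.

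Alternatives fixed before the data were examined covered the scaling, background correction, signal column, probe summary, filter, floor, variance model, array weights, replicate block, the authors' value table and leaving out each array. The planned normexp correction used median signals, because the files hold no column of mean signals. Slide and scan could not be used as a block because all arrays shared 1 slide and 1 scan, and slide column coincides with age. Chosen after seeing the data were spike-in scaling, cyclic loess, slide row as a block, and P10 replicates 3 and 4 or 2 and 4 alone. Cyclic loess was first run over all probes and gave 34 calls. A version with curves fitted on bright probes (those above background on all arrays) was added after that result had been seen, and both are reported.

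Only the limma step was tested, on 20 simulations of the adult against P10 comparison with 238 miRNAs, 80 of them changed. Log2 values were drawn independently for each miRNA, with the same SD in both ages. Scaling, floor, probe choice and effects shared by an array were not simulated. There limma called 74.0% of 2-fold and 91.6% of 4-fold changes, 4.33% of calls were unchanged miRNAs, and 0 called changes had the wrong sign. These rates were not shown to hold for the real arrays, whose calls depended on scaling. No pair of arrays held identical values (highest correlation 0.997).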

Results

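MicroRNAs (miRNAs) were measured in pancreatic islets of Sprague Dawley rats on 1-colour Agilent arrays. Islets are the endocrine cell clusters of the pancreas, in which insulin-secreting beta cells are the main cell type. RNA came from rats 10 days old (P10, 4 arrays) and from males 3 months old (adult, 4 arrays), and the labels call each array a biological replicate without saying how many animals gave its islets. The labels do not give the sex of the P10 rats, so sex was not shown to be equal between the ages. The title of the series names beta-cell maturation as the question. The 75th percentile signal of the probes above background on all 8 arrays was 388, 440, 989 and 1690 on P10 replicates 1 to 4, and 1354, 1401, 1677 and 1284 on adult replicates 1 to 4. Of 677 rat miRNAs on the array, 213.8 ± 24.5 (SD, n = 4) were well above background per P10 array and 238.5 ± 14 (SD, n = 4) per adult array, a difference with an exact two-sided permutation p of 0.171. All 8 arrays lay on 1 slide, P10 in 1 column and adult in the other, so slide column and age cannot be told apart. Names are given without the species prefix rno, and an asterisk marks the minor arm of a hairpin as the array names it.

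Under the scaling used here, adult islets held more of the miR-29 family, miR-7a, miR-204, miR-22 and the miR-23/27/24 group than P10 islets. They held less of the miR-17~92 group, the miR-181 family, miR-130b and miR-192, miR-194 and miR-215. Several of these calls, among them miR-7a and the miR-23/27/24 group, were lost under other scalings, as given below. Of 238 miRNAs tested, 113 differed between the ages (limma, Benjamini-Hochberg adjusted p under 0.05), 65 of them higher and 48 lower in adult. At least a 2-fold difference was found for 62, of which 29 were higher and 33 lower. The 2 ages did not overlap for 109 of the tested miRNAs (45.8%), where chance gives 2.86%. The mean correlation between arrays was 0.994 within adult, 0.918 within P10 and 0.853 between ages. The P10 arrays formed pairs, with replicates 1 and 2 at 0.974 and replicates 3 and 4 at 0.965. P10 replicate 4 lay closer to every adult array (0.9084 to 0.9255) than to P10 replicates 1 and 2 (0.859 and 0.899). The within-age mean exceeded the between-age mean by 0.103 (exact one-sided permutation p = 0.0286, the smallest that 35 splits allow). Without any 1 adult array this p was 0.0571. There 35 splits remained, so a split that mixed the ages separated the arrays at least as well.

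The split into higher and lower calls depended on how arrays were scaled. It was 65 to 48 here, 90 to 34 with the percentile taken over all probes, 61 to 17 without scaling, 50 to 9 with spike-in scaling, 33 to 46 with normexp and 13 to 21 with cyclic loess over all probes, and 42, 42 and 43 were higher without adult replicate 1, 2 or 3. Of 59 named miRNAs that passed here, 34 lost their call with cyclic loess over all probes, 19 with spike-in scaling, 13 without scaling and 9 with quantile normalization, apart from those that turned sign. The median log2 difference of the tested miRNAs was -0.01 here and 0.45, 0.94, 0.99, -0.30 and 0.16 in those settings, so each difference below is relative to the bulk of measured miRNAs.

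**Figure D1:**
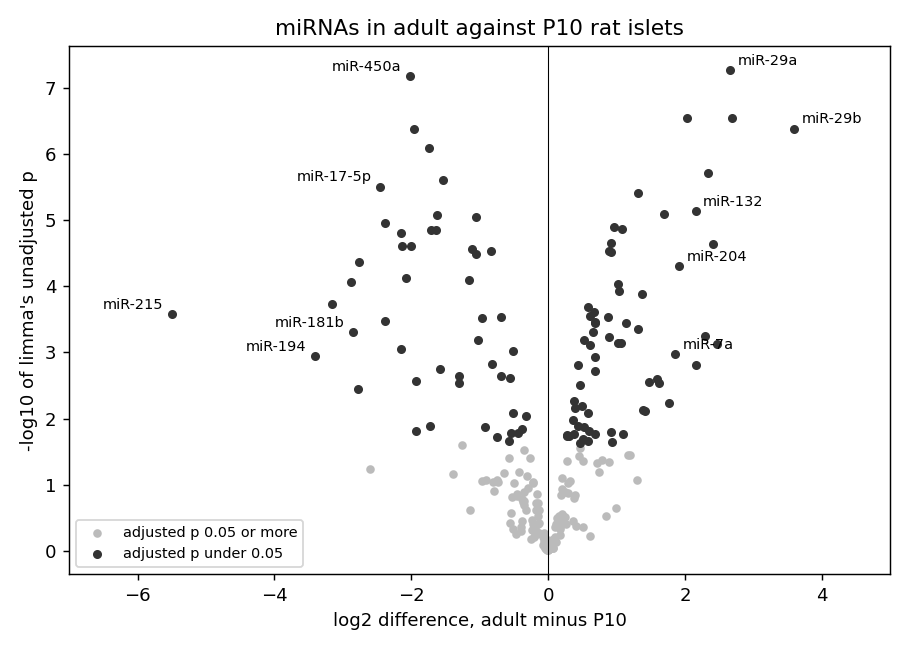
Log2 difference between adult and P10 islets (x axis) against -log10 of limma's unadjusted p (y axis) for the 238 tested miRNAs. Dark points are the 113 with an adjusted p under 0.05, of which 65 lie to the right and 48 to the left under the scaling used.

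The miR-29 family, known to act on extracellular matrix and membrane fusion genes, held the largest increases. All 4 tested members rose (4 adjusted over the list alone): miR-29b by 3.59 ± 0.24 (log2 difference ± SE, n = 4 per age), a 12.1-fold difference with a limma adjusted p of 1.63e-05 and all 4 adult arrays above all 4 P10 arrays, miR-29c by 2.68, miR-29a by 2.66 and miR-29c* by 2.02. Of these, miR-29c* was well above background on only 2 of 4 P10 arrays, so that its size rests in part on signal near background. The list stood above the other miRNAs (camera adjusted p = 0.000725, and adjusted p = 0.458 with an estimated correlation). Its call also ended with cyclic loess over all probes (adjusted p = 0.0688, in a range of 2.98e-06 to 0.458 over 28 alternatives). In that setting miR-29b (1.37), miR-29a (0.84) and miR-29c (1.14) also lost their own calls, with limma adjusted p of 0.157, 0.151 and 0.136, while miR-29c* kept its call.

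Of 10 tested islet endocrine miRNAs, 8 rose in adult and none fell (8 and 0 adjusted over the list alone). Among the 8 were miR-29a (2.66), counted above in the miR-29 family, and the related products miR-7a, miR-7a-1*, miR-7a-2* and miR-7b. The list is therefore not independent of the miR-29 list, and its members are not independent of each other. miR-204 rose 3.77-fold (log2 difference 1.91 ± 0.24 SE, limma adjusted p = 0.000371, n = 4 per age) and miR-7a, among the most abundant islet miRNAs, rose 3.61-fold (1.85 ± 0.37 SE, adjusted p = 0.00394). The call of miR-7a was lost with quantile normalization (1.05), in the authors' value table (0.84) and with cyclic loess over all probes (0.71). miR-153 rose by 1.61 (0.89 and not called with cyclic loess over all probes, and lost without a filter) and miR-7a-1* by 0.67 (turning to -0.11 with normexp). miR-375, the best known islet miRNA, was at 3.27 ± 0.30 (SD) in P10 and 3.73 ± 0.14 in adult. Its difference of 0.47 passed the limma threshold narrowly (adjusted p = 0.0485), lost its call without P10 replicate 1 (0.30) or 2 (0.43) or any 1 adult array (0.41 to 0.51), and turned to -0.32 with quantile normalization, -0.41 in the authors' value table and -0.28 with cyclic loess on bright probes. miR-184 was not well above background on any adult array and was not tested. The list had a camera adjusted p of 0.00501, with adjusted p = 0.458 with an estimated correlation, 0.0927 with quantile normalization, 0.102 in the authors' value table and 0.0509 without scaling (4.36e-05 to 0.458 over 28 alternatives). P10 replicates 1 and 2, the dimmest arrays, had the lowest miR-7a (1.89 and 2.95, against 3.54 and 3.70 on replicates 3 and 4). The same 2 arrays had the lowest P10 values of miR-375, miR-204 and miR-153 and the highest values of acinar miR-216a (-0.60 and -0.91, against -4.77 and -5.51) and miR-217 (-3.04 and -3.33, against the floor).

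**Figure D2:**
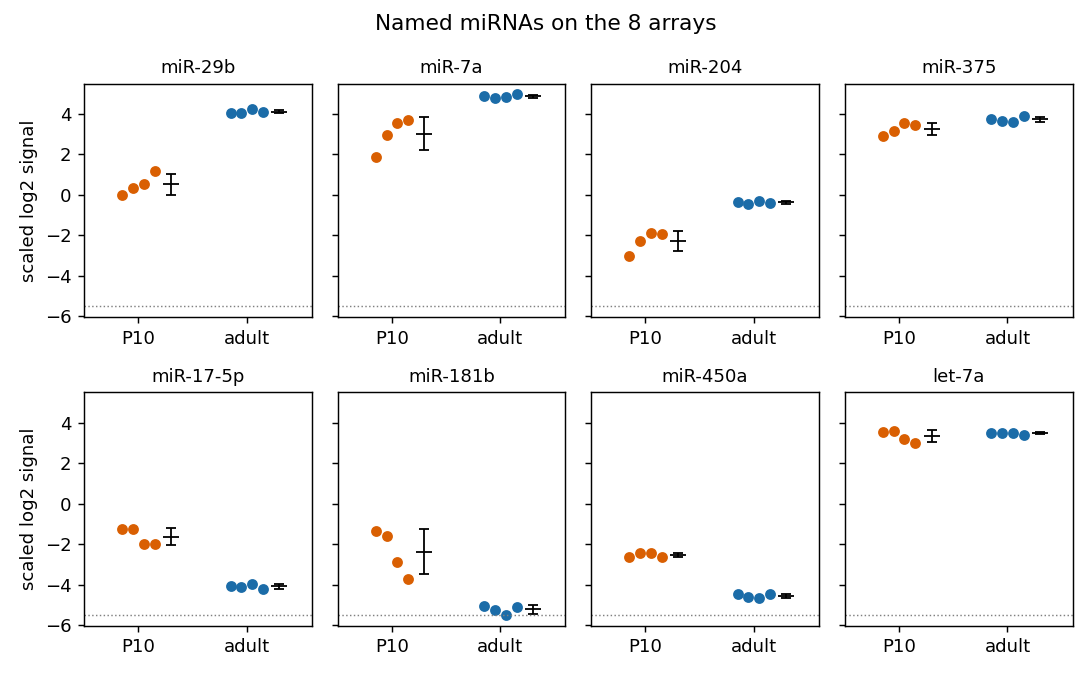
Scaled log2 signal of 8 named miRNAs on each array (points), with the mean and SD of each age (bars, n = 4) and the floor (dotted line). miR-29b, miR-7a and miR-204 are higher and miR-17-5p, miR-181b and miR-450a lower on every adult array, whereas miR-375 and let-7a turn direction between scalings.

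The miR-17~92 group and its paralogues, known for promoting cell proliferation, fell as a whole. All 10 tested members were lower in adult (10 adjusted over the list alone), from miR-17-5p, which fell 5.47-fold (log2 difference -2.45 ± 0.21 SE, limma adjusted p = 7.47e-05, n = 4 per age, with its other probe at -1.30), and miR-20b-5p (-2.16), miR-92a (-2.14) and miR-20a (-2.14) to miR-25 (-1.30) and miR-106b (-1.16). Each of the 10 was higher on P10 replicates 1 and 2, the dimmest arrays and those with the most acinar miR-216a, than on replicates 3 and 4, as with miR-92a (1.49 and 1.34, against 0.06 and -0.33) and miR-25 (0.87 and 0.77, against -0.19 and -0.38). The camera adjusted p was 3.37e-06, with adjusted p = 0.458 with an estimated correlation, and 27 of 28 alternatives passed. With spike-in scaling miR-20a (-1.13), miR-20b-5p (-1.15), miR-25 (-0.29) and miR-106b (-0.15) lost their own calls, and miR-17-5p (-1.69) did with cyclic loess over all probes. The X-linked cluster had 2 tested members, miR-450a (-2.02) and miR-322 (-1.06), and both fell. Both lost their call without scaling (-1.06 and -0.097) and with spike-in scaling (-1.01 and -0.048), and miR-322 also with the percentile over all probes (-0.59) and with cyclic loess over all probes (-0.64).

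The miR-181 family, known from lymphocyte development, fell in all 4 tested members (4 adjusted over the list alone). miR-181b fell 7.20-fold (-2.85 ± 0.50 SE, limma adjusted p = 0.00224, n = 4 per age), and miR-181a (-2.39), miR-181c (-2.38) and miR-181d fell as well, miR-181d to the floor on 3 of 4 adult arrays, so that no size is given. With cyclic loess over all probes miR-181b (-2.27), miR-181a (-1.58) and miR-181d lost their own calls. The camera adjusted p was 0.00651, with adjusted p = 0.458 with an estimated correlation, and 27 of 28 alternatives passed. On P10 replicates 1 to 4 miR-181b lay at -1.34, -1.59, -2.91 and -3.70, all above the adult values of -5.04 to -5.50. miR-130b also fell, by 2.88 (7.37-fold). All 4 miR-181 members and miR-130b were higher on P10 replicates 1 and 2 than on replicates 3 and 4. Replicates 1 and 2 were the dimmest arrays and had the most acinar miR-216a. Chance was not excluded for the number of lists past the threshold (8 of 35 splits of the arrays gave at least 5).

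The miR-23/27/24 group rose in all 5 tested members (5 adjusted over the list alone), with miR-23b at 1.31, miR-24 at 1.04, miR-23a at 0.69 and miR-27a at 0.43, the last lost without P10 replicate 1 (0.30) or 2 (0.39) or any 1 adult array (0.41 to 0.46). With quantile normalization and with cyclic loess over all probes miR-23b (0.55 and 0.32), miR-24 (0.51 and 0.42), miR-23a (0.23 and 0.28) and miR-27a (0.29 and 0.33) lost their own calls. Its camera adjusted p was 0.00651, with adjusted p = 0.458 with an estimated correlation, and the call ended in 8 other settings, among them 0.263 with quantile normalization and 0.0574 with P10 replicates 3 and 4 alone (0.000261 to 0.458 over 28 alternatives). The lowest values of miR-23a, miR-23b, miR-24 and miR-27a lay on P10 replicates 1 and 2, the dimmest arrays and those with the most acinar miR-216a. For miR-24 they were 0.95 and 1.25, against 1.45 and 1.58 on replicates 3 and 4. miR-22 rose 3.21-fold (1.68 ± 0.16 SE, limma adjusted p = 0.000141, n = 4 per age) and miR-384-5p 4.48-fold (2.17), and both lost their call with cyclic loess over all probes (0.57 and 1.20). The size for miR-384-5p leans on P10 replicates 1 and 2 (-3.4 and -2.14, against -1.27 and -1.19 on replicates 3 and 4).

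Other families moved in part. In the cluster of miR-183, miR-96 and miR-182, known from sensory and endocrine cells, miR-183 (1.07) and miR-96 (0.96, -0.041 with cyclic loess over all probes) rose and miR-182 (0.28, -0.038 with normexp) did not pass but passed in 6 alternatives (0.39 to 0.74), while all 3 passed adjusted over the list alone (camera adjusted p = 0.0873). miR-132 rose (at the floor on P10 replicates 1 and 2, so that no size is given, and not called with normexp) and its cluster partner miR-212 stood at 0.26 (adjusted p = 0.504, limma) and passed in 6 alternatives (0.56 to 1.27). In the let-7 family, known to increase with differentiation, 3 of 10 tested members rose (3 adjusted over the list alone): miR-98 (1.02, lost with cyclic loess over all probes, 0.43), let-7e (1.01, lost there, 0.39, with quantile normalization, 0.58, and in the authors' value table, 0.71) and let-7f (0.38, called in the opposite direction with cyclic loess on bright probes, at -0.36 with a limma adjusted p of 0.0208, and lost without adult replicate 1, 2 or 3, at 0.37 each). let-7a (0.15) and let-7b (0.17) did not pass here and were called in both directions elsewhere. let-7a was called lower in adult in 3 alternatives (-0.57 to -0.46) and higher in 3 (0.43 to 1.11), and let-7b lower in the authors' value table (-0.51) and higher in 4 alternatives (0.59 to 1.18). In the miR-200 family of epithelial cells, miR-200c (0.87, lost with cyclic loess over all probes, 0.16) and miR-141 (0.47, called in the opposite direction with quantile normalization, at -0.35 with a limma adjusted p of 0.0213) rose and the other 3 did not pass. In the miR-30 family 1 of 9 rose, miR-30b-5p (0.62, lost with quantile normalization, 0.31, with spike-in scaling, 1.63, and with cyclic loess over all or on bright probes, 0.11 and 0.25), and the list's median (-0.06), mean (0.0063) and test (Down) differed in sign. In the group of miR-99, miR-100 and miR-125 products 1 of 7 fell, miR-100 (-0.58, turning to 0.38 without scaling), and 0 adjusted over the list alone. The call of miR-100 was lost without P10 replicate 1 (-0.48) or 2 (-0.50) or any 1 adult array (-0.66 to -0.52). miR-34a, the 1 tested member of its family, was at -0.05, and was called higher in 3 alternatives (0.67 to 0.96) and lower with array weights (-0.51).

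Members of the imprinted Dlk1-Dio3 locus went both ways. Of 39 tested, 8 rose and 4 fell (5 and 3 adjusted over the list alone). Among those that passed, miR-495 (0.92) and miR-376b-5p (0.89) rose most (0.047 and 0.080 and not called with normexp). miR-299 (-1.06, but 2.48 and not called with cyclic loess over all probes) and miR-379 (-0.69, turning to 0.27 without scaling) fell most among them. The lowest value in the list was that of miR-494 (-2.61), which did not pass. Both miR-495 and miR-376b-5p were well above background on only 2 of 4 P10 arrays, so that their sizes rest in part on signal near background. The list's test pointed up while its mean was -0.04 and its median -0.02 (camera adjusted p = 0.96).

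**Figure D3:**
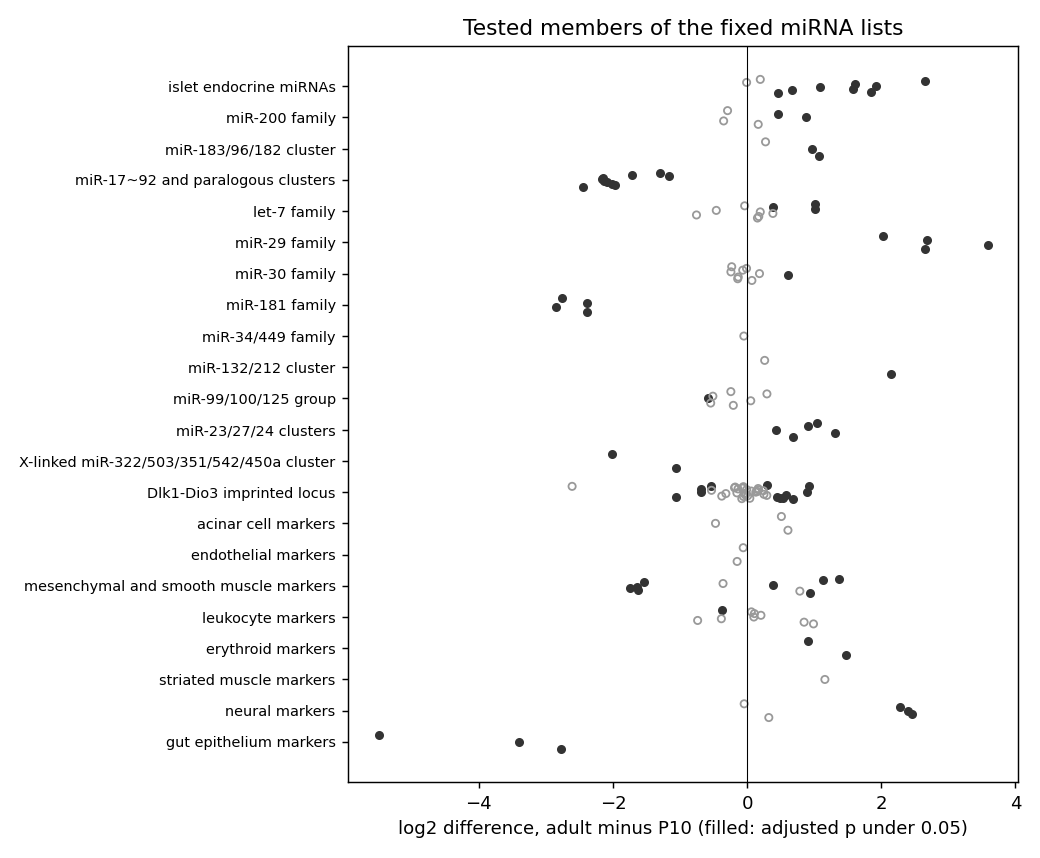
Log2 difference between adult and P10 islets (x axis) for each tested member of the fixed lists (rows), filled where the adjusted p was under 0.05. All members of the miR-29 family lie to the right and all members of the miR-17~92 group and the miR-181 family to the left.

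Markers of other cell types differed between ages and between arrays of 1 age. The gut epithelium markers all fell: miR-215 was at least 43.5-fold lower in adult, where no array had it well above background (limma adjusted p = 0.00151), miR-194 was 10.6-fold lower (-3.41 ± 0.69 SE) and miR-192 6.88-fold lower (-2.78 ± 0.68 SE, n = 4 per age). With spike-in scaling miR-194 (-2.40) and miR-192 (-1.77) lost their own calls. On P10 replicates 1 to 4 miR-215 lay at 1.02, -2.51, 2.07 and -0.64. The list did not pass (camera adjusted p = 0.0647) but passed in 7 other settings, among them spike-in scaling (0.000205, in a range up to 0.458 over 21 alternatives). Acinar miR-216a was at -0.60 and -0.91 on P10 replicates 1 and 2, at -4.77 and -5.51 on replicates 3 and 4 and between -2.77 and -1.74 in adult, and none of the 3 acinar markers passed. With P10 replicates 3 and 4 alone, on which they lay at or near the floor, miR-216a and miR-217 passed as higher in adult, and miR-217 also did without scaling (1.59) and with spike-in scaling (1.71). The difference of miR-216a was 0.61 on its brightest probe, 0.13 on another and -0.73 on a dimmer one. The latter probes were at the floor on P10 replicates 3 and 4, and the dimmer one also on adult replicate 3. The floor therefore sets part of these differences, and their signs do not show that the probes disagree.

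Among mesenchymal markers, miR-199a-5p (-1.75) and miR-214 (-1.64) fell (-0.79 and -0.68 and not called without scaling) while miR-195 (1.36) and miR-497 (1.14) rose, and miR-143 (0.93) passed narrowly (limma adjusted p = 0.0485) and lost its call without any 1 array except P10 replicate 4 (0.69 to 1.06). In all 4 of 10 rose and 4 fell (5 and 4 adjusted over the list alone), with a median of 0.01, a mean of -0.23 and a test pointing down. The erythroid miR-451 (1.47) and miR-144 (0.91, with 2 P10 arrays and 1 adult array at the floor, turning to -0.32 with normexp) rose, with adult replicate 4 apart at -2.13 for miR-451. The call of miR-144 was lost without P10 replicate 1, 2 or 3 (0.87, 0.96 and 0.89) or adult replicate 1, 2 or 3 (0.75, 0.87 and 0.79). Of 9 leukocyte markers, miR-342-5p fell (all 4 adult arrays were at the floor, which sets the -0.38, and it was 0.18 with cyclic loess on bright probes, lost without P10 replicate 2 or any 1 adult array, at -0.41 to -0.32), with none past the threshold adjusted over the list alone, and the list's median of 0.10 and mean of 0.09 opposed its test, which pointed down. By detection miR-342-5p showed no fall, being well above background on 3 adult arrays and 2 P10 arrays. P10 replicate 4 held the leukocyte miR-142-3p at 1.36, against -2.22 to -1.67 on the other P10 arrays. Without it miR-142-3p (1.83), miR-145 (1.11), miR-133b (1.69) and miR-142-5p (at the floor on the other 3 P10 arrays) passed (limma). Endothelial miR-126 (-0.15) and miR-126* (-0.06) did not pass and turned sign in several scalings, while miR-126 was called lower with quantile normalization (-0.79) and with P10 replicates 3 and 4 alone (-0.53), and miR-126* with normexp (-0.46). Striated muscle miR-133b (1.16, with 2 P10 arrays at the floor) did not pass (limma adjusted p = 0.0728), passed adjusted over the list alone, which for this 1 tested member is its unadjusted p of 0.0361, passed in 4 alternatives and was -0.089 with normexp. In the neural list, miR-129 (2.46, with 1 P10 array at the floor), miR-129-1* (2.40) and miR-129-2* (2.29) rose, with other probes at 2.01, 0.33 and 0.74, and 2 others did not pass (camera adjusted p = 0.0879). On P10 arrays miR-129 was well above background on only 2 of 4, and miR-129-1* and miR-129-2* on 3 each. Each of these miR-129 products was lower on P10 replicates 1 and 2, the dimmest arrays, than on replicates 3 and 4. The hepatocyte marker was not tested.

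**Figure D4:**
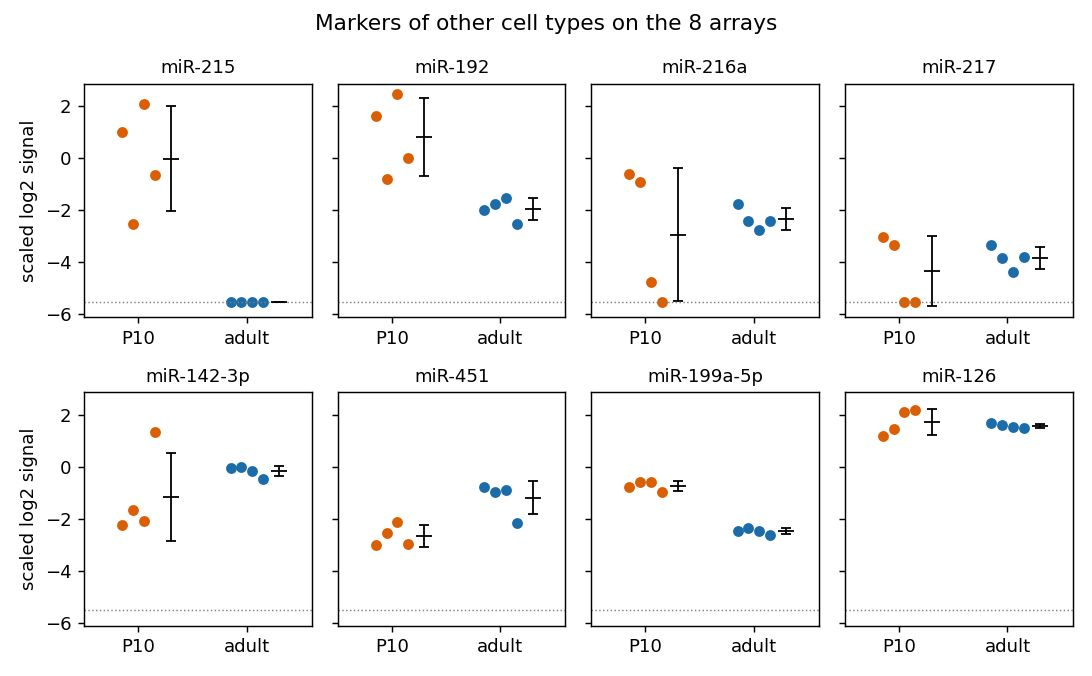
Scaled log2 signal of 8 markers of other cell types on each array (points), with the mean and SD of each age (bars, n = 4) and the floor (dotted line). miR-215 is at the floor on every adult array, and miR-216a separates P10 replicates 1 and 2 (-0.60 and -0.91) from replicates 3 and 4 (-4.77 and -5.51).

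miR-384-3p, miR-22* and miR-383 were well above background on every adult array and on no P10 array. The lowest signal well above background was -4.11 and -4.27 on P10 replicates 1 and 2, above every adult value of these 3. Detection on those arrays was thus not possible at the adult level. On replicates 3 and 4 that limit was -5.81 and -5.55. miR-384-3p was at least 1.02-fold higher in adult, and no fold is given for the others because their bound was under 1. All 3 turned below 0 with normexp (-0.30, -0.33 and -0.35).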

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

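The tests of explanations in this part were chosen after the values had been seen. Of 148 groups of 4 values, 13 held an array far from the other 3, of which 5 lay on P10 replicate 4 and 5 on adult replicate 4. The rate of 1 in 20 by chance does not hold for groups with arrays at the floor, and in miR-184, miR-142-5p and miR-181d the other 3 arrays were all there, so that any value above it counts. Among the 137 groups without an array at the floor there were 9, where 1 in 20 gives 6.85. On P10 replicate 4 these were miR-142-3p at 1.36 (others -2.22 to -1.67), miR-142-5p at -2.07 (others -5.51), miR-133b at -3.47, miR-376b-5p at -3.59 and miR-184 at -4.72. On adult replicate 4 they were miR-451 at -2.13 (others -0.97 to -0.75), miR-143 at 2.13, miR-195 at -0.49, miR-92a at -1.80 and the hybridisation spike-in at 14.31. The others were miR-132 at -3.29 on adult replicate 1, miR-384-3p at -5.10 on adult replicate 2 and miR-181d at -5.45 on adult replicate 3.

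The P10 arrays were dimmer by 0.96 on the log2 scale (1.95-fold). Lower labelling or hybridisation efficiency is argued against by the labelling spike-in, whose adult minus P10 difference was -0.0579, against a signal deficit of 0.96. The dim arrays do not account for all of the calls, since 83.8% of the 111 calls that could be tested kept sign and threshold with P10 replicates 3 and 4 alone. Age stays open (exact permutation p = 0.143, with P10 replicate 4 as bright as the adult arrays), and so does the amount of miRNA in the RNA, for which no measure was used here.

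miR-192, miR-194 and miR-215 were higher and uneven in P10. Acinar carry-over as the whole cause is argued against by 2 of the 4 P10 arrays, which had miR-215 above and miR-216a below all adult arrays. Scaling of dim arrays as the whole cause is argued against by a mean difference of -3.05 with spike-in scaling, against -3.89. A part is not excluded. In that setting miR-194 (-2.40) and miR-192 (-1.77) lost their own calls, and the mean leans on miR-215, which was at the floor on every adult array. Carry-over of another epithelium cannot be told apart from an effect of age, because the miR-200 family (mean difference 0.17) is abundant in islets and would hide a small share.

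The P10 arrays lay at unequal distance from adult, with correlations to the adult mean of 0.774, 0.848, 0.878 and 0.922 on replicates 1 to 4, a range of 0.148. Floored values are argued against, since the range was 0.148 over miRNAs above background on all 8 arrays. A trend with brightness cannot be told apart from other causes: cyclic loess on bright probes left a range of 0.11. No biological explanation was tested, as the labels give no difference among P10 samples.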

How the results depend on the processing

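The cluster of miR-183, miR-96 and miR-182 is called the miR-183 cluster here, and the group of miR-99, miR-100 and miR-125 products the miR-99 group. Settings chosen after seeing the data were spike-in scaling, both forms of cyclic loess, slide row as a block, and P10 replicates 3 and 4 or 2 and 4 alone. Slide or scan as a block was not run, since all arrays shared 1 slide and 1 scan. A result counts as turned whenever its sign or, for a list, its test's direction differs, also where it passed in neither fit (44 of the turned miRNA values). Of 59 named called miRNAs, 9 kept sign and call in each alternative that gave them a value. Of these 5 had a value in all 27 (miR-130b, miR-181c, miR-204, miR-497 and miR-92a), miR-129, miR-129-1* and miR-29c* in 26 and miR-215 in 20. In all 46 kept their sign wherever they had a value. Leaving out cyclic loess over all probes, these were 24 and 48. Called in opposite directions were miR-141 with quantile normalization and let-7f with cyclic loess on bright probes. Causes were not tested unless stated. Signal over background limits the dimmest miRNAs, near the floor.

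The count of 113 became 34 with cyclic loess over all probes (13 higher, 21 lower, 32 of the 112 calls tested kept), whereas cyclic loess on bright probes, added after that, gave 117 (72 and 45, 90 of 113 kept). The former also fits values at the floor, which was not shown to be the cause. It became 59 with spike-in scaling (9 lower), 179 with array weights (91 lower) and 62 at 2-fold or more (29 higher). The lower calls were 17 without scaling, and the higher calls were 33 with normexp, 43 above background on all 8 arrays (164 tested) and 43 at an adjusted p under 0.01. Leaving out an array gave 80 to 138 calls, with 42 to 79 higher (42, 42 and 43 without adult replicates 1, 2 and 3) and 38 to 59 lower. The separation of ages was 0.0824 to 0.133 without 1 array. Its exact permutation p was 0.0571 without any 1 adult array, where a split that mixed the ages separated the arrays at least as well. The separation was 0.0764 and 0.0946 with P10 replicates 3 and 4 or 2 and 4, where 15 splits cannot reach 0.05.

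The replicate block gave 95 calls (51 higher, 44 lower) and called the gut list (-3.89, adjusted p = 0.0398). No clear pairing by number was seen: same-number deviations correlated at 0.177, -0.0897, 0.475 and -0.23, and 3 arrays correlated best with their own number. These few values cannot exclude a pairing, which the labels do not state. Slide row as a block gave 90 and turned the Dlk1-Dio3 list (-0.039).

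With an estimated correlation the lists lost were islet (1.20), miR-17~92 (-1.91), miR-29 (2.74), miR-181 (-2.60) and miR-23/27/24 (0.88). fry does not compare a list with other miRNAs, so it is left out of the counts and ranges in the report. It called miR-183 cluster (0.77), let-7 (0.21), mesenchymal (-0.23), neural (1.49) and gut (-3.89).

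With quantile normalization islet (1.00) and miR-23/27/24 (0.39) lost their call. Turned were the lists miR-200 (-0.21), let-7 (-0.13), miR-30 (0.082) and leukocyte (0.26), and miR-375 (-0.32), let-7a (-0.46), let-7b (-0.45), let-7f (-0.18), miR-141 (-0.35), miR-34a (0.11) and miR-126* (0.27). The median moved to 0.11.

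In the authors' value table islet (0.71) and miR-23/27/24 (0.56) lost it, and miR-183 cluster (0.89) and gut (-3.12) gained it. Turned were miR-200 (0.019), let-7 (-0.12), miR-30 (0.095) and leukocyte (0.24), and miR-375 (-0.41), let-7a (-0.57), let-7b (-0.51), let-7f (-0.24), miR-141 (-0.16), miR-34a (0.092) and miR-126* (0.12).

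With cyclic loess over all probes islet (0.74), miR-29 (1.21) and miR-23/27/24 (0.33) lost it, and neural (1.59) gained it. Turned were miR-200 (-0.36), let-7 (0.39) and leukocyte (0.45), and let-7a (-0.41), let-7b (-0.31), let-7f (-0.17), miR-141 (-0.20), miR-96 (-0.041), miR-299 (2.48), miR-126* (0.039) and miR-342-5p (0.015).

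With cyclic loess on bright probes islet (0.98) and miR-23/27/24 (0.41) lost it, and neural (1.73) and gut (-3.87) gained it. Turned were miR-200 (-0.21), let-7 (-0.072), miR-30 (0.12) and leukocyte (0.31), and miR-375 (-0.28), let-7a (-0.57), let-7b (-0.46), let-7f (-0.36), miR-141 (-0.20), miR-126* (0.29) and miR-342-5p (0.18). The median moved to 0.20.

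Without scaling islet (2.11) and miR-23/27/24 (1.84) lost it and gut (-3.06) gained it. Turned were miR-30 (0.90), miR-99 group (0.71) and leukocyte (0.89), and miR-126 (0.81), miR-126* (0.90), miR-34a (0.91), miR-100 (0.38) and miR-379 (0.27). With spike-in scaling miR-23/27/24 (1.89) lost it and gut (-3.05) gained it. Turned were miR-30 (0.95), miR-99 group (0.76) and leukocyte (0.94), and miR-126 (0.86), miR-126* (0.95), miR-34a (0.96), miR-100 (0.43) and miR-379 (0.32). With the percentile over all probes miR-23/27/24 (1.35) lost it and gut (-3.46) gained it. Turned were miR-30 (0.45) and leukocyte (0.50), and miR-126 (0.32), miR-126* (0.41) and miR-34a (0.42).

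With normexp on median signals miR-183 cluster (0.56), let-7 (0.20) and neural (0.68) gained it. Turned were miR-30 (-0.16) and Dlk1-Dio3 (-0.38), and miR-384-3p (-0.30), miR-22* (-0.33), miR-383 (-0.35), miR-212 (-0.28), miR-182 (-0.038), miR-217 (-0.19), miR-142-5p (-0.36), miR-145 (-0.27), miR-7a-1* (-0.11), miR-144 (-0.32) and miR-133b (-0.089).

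Array weights turned acinar (-1.02), mesenchymal (-0.082) and leukocyte (0.28), and miR-212 (-0.16), miR-216a (-1.07), miR-217 (-0.35), miR-126 (0.13), miR-126* (0.23), let-7a (-0.046) and let-7b (-0.10). Total gene signal called gut (-4.26) and turned miR-30 (0.093), leukocyte (0.22), miR-34a (0.016) and miR-126* (0.064). The mean over probes turned acinar (-0.019). No filter called miR-183 cluster (0.46) and turned miR-30 (-0.0010) and leukocyte (0.068). The filter on all 8 arrays turned miR-30 (0.061), Dlk1-Dio3 (-0.10) and leukocyte (0.12). P10 replicates 3 and 4 alone ended miR-23/27/24 (0.80) and turned miR-30 (0.29), miR-99 group (0.25), Dlk1-Dio3 (-0.024) and miR-34a (0.67). P10 replicates 2 and 4 alone turned miR-30 (0.013), Dlk1-Dio3 (-0.20), miR-142-3p (-0.041), miR-142-5p (-0.082) and miR-34a (0.050).

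Without 1 array, ranges that crossed 0 were miR-30 -0.082 to 0.080, Dlk1-Dio3 -0.10 to 0.041, acinar -0.34 to 0.80, leukocyte -0.013 to 0.30, miR-216a -0.24 to 1.39, miR-126 -0.37 to 0.0093, miR-126* -0.26 to 0.14, let-7b -0.0053 to 0.29 and miR-34a -0.30 to 0.21. Calls lost without 1 array are named with their values beside miR-375, miR-27a, let-7f, miR-100, miR-143, miR-144 and miR-342-5p in the report, and miR-142-3p (1.83), miR-142-5p (1.77, set by the floor), miR-145 (1.11) and miR-133b (1.69) gained a call without P10 replicate 4. The 5 called lists kept their calls without any 1 array.

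Named miRNAs that lost their own call and kept their sign numbered 34 with cyclic loess over all probes and 19 with spike-in scaling, and 13 or fewer elsewhere. With the percentile over all probes, these were miR-100 (-0.11), miR-322 (-0.59), miR-342-5p (-0.13) and miR-379 (-0.22). Lost in the authors' value table were let-7e (0.71), miR-100 (-0.39), miR-143 (0.62), miR-23a (0.50), miR-27a (0.44), miR-342-5p (-0.23) and miR-7a (0.84). With cyclic loess over all probes, these were let-7e (0.39), miR-100 (-0.24), miR-106b (-0.88), miR-129-2* (1.61), miR-143 (0.52), miR-144 (3.48), miR-153 (0.89), miR-17-5p (-1.69), miR-181a (-1.58), miR-181b (-2.27), miR-181d (-1.40), miR-183 (0.63), miR-192 (-1.46), miR-195 (0.59), miR-200c (0.16), miR-22 (0.57), miR-23a (0.28), miR-23b (0.32), miR-24 (0.42), miR-25 (-0.81), miR-27a (0.33), miR-29a (0.84), miR-29b (1.37), miR-29c (1.14), miR-30b-5p (0.11), miR-322 (-0.64), miR-375 (0.018), miR-376b-5p (0.71), miR-379 (-0.96), miR-384-3p (0.36), miR-384-5p (1.20), miR-495 (0.59), miR-7a (0.71) and miR-98 (0.43). Lost with cyclic loess on bright probes were miR-143 (0.43), miR-23a (0.30), miR-27a (0.14) and miR-30b-5p (0.25). With 0.5 of the floor, this was miR-375 (0.47). Lost with the mean over probes were miR-141 (0.31), miR-143 (0.95), miR-144 (0.46), miR-27a (0.38), miR-342-5p (-0.094) and miR-384-3p (0.17). Without a filter, these were miR-100 (-0.58), miR-143 (0.93), miR-144 (0.91), miR-153 (1.61), miR-192 (-2.78), miR-25 (-1.30), miR-27a (0.43), miR-342-5p (-0.38), miR-375 (0.47) and miR-451 (1.47). Lost without scaling were miR-106b (-0.20), miR-143 (1.89), miR-144 (1.16), miR-192 (-1.82), miR-199a-5p (-0.79), miR-214 (-0.68), miR-25 (-0.34), miR-27a (1.39), miR-299 (-0.097), miR-322 (-0.097), miR-342-5p (-0.073), miR-375 (1.43) and miR-450a (-1.06). With normexp, these were miR-100 (-0.60), miR-132 (0.55), miR-143 (0.95), miR-27a (0.41), miR-342-5p (-0.68), miR-375 (0.52), miR-376b-5p (0.080) and miR-495 (0.047). Lost with P10 replicates 2 and 4 were miR-143 (0.68), miR-144 (0.83), miR-27a (0.31), miR-375 (0.39) and miR-376b-5p (0.72). With P10 replicates 3 and 4, these were miR-100 (-0.22), miR-143 (0.43), miR-144 (0.97), miR-27a (0.28), miR-375 (0.27) and miR-379 (-0.45). Lost with quantile normalization were let-7e (0.58), miR-143 (0.45), miR-23a (0.23), miR-23b (0.55), miR-24 (0.51), miR-27a (0.29), miR-30b-5p (0.31), miR-342-5p (-0.13) and miR-7a (1.05). With the replicate block, these were let-7f (0.38), miR-143 (0.93), miR-144 (0.91), miR-27a (0.43), miR-342-5p (-0.38) and miR-375 (0.47). Lost with slide row were let-7f (0.38), miR-100 (-0.58), miR-27a (0.43), miR-342-5p (-0.38) and miR-375 (0.47). With spike-in scaling, these were let-7f (1.39), miR-106b (-0.15), miR-143 (1.94), miR-144 (1.25), miR-192 (-1.77), miR-194 (-2.40), miR-199a-5p (-0.74), miR-20a (-1.13), miR-20b-5p (-1.15), miR-214 (-0.63), miR-23a (1.70), miR-25 (-0.29), miR-27a (1.44), miR-299 (-0.048), miR-30b-5p (1.63), miR-322 (-0.048), miR-342-5p (-0.064), miR-375 (1.47) and miR-450a (-1.01). Lost with total gene signal was miR-342-5p (-0.27).

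Named miRNAs that did not pass here gained a call with the same sign in 10 settings other than those without 1 array. Gained with the percentile over all probes were let-7a (0.62), let-7b (0.64), miR-133b (1.28), miR-145 (1.00), miR-182 (0.74) and miR-212 (0.73). With array weights, these were miR-133b (1.73), miR-142-3p (1.57), miR-142-5p (1.66), miR-145 (1.17) and miR-34a (-0.51). Gained in the authors' value table were miR-182 (0.52) and miR-212 (0.56). With cyclic loess on bright probes, these were miR-133b (1.44), miR-145 (1.17), miR-182 (0.41) and miR-212 (0.84). Gained without scaling were let-7a (1.11), let-7b (1.13), miR-212 (1.22) and miR-217 (1.59). With normexp, this was miR-126* (-0.46). Gained with P10 replicates 3 and 4 were let-7a (0.43), let-7b (0.59), miR-126 (-0.53), miR-182 (0.39), miR-212 (0.81), miR-216a (2.92) and miR-217 (1.82). With quantile normalization, these were miR-126 (-0.79) and miR-182 (0.39). Gained with spike-in scaling were let-7b (1.18), miR-212 (1.27) and miR-217 (1.71). With total gene signal, this was miR-182 (0.41). Called against their sign here, from no call, were let-7a with quantile normalization, in the authors' value table and with cyclic loess on bright probes, let-7b in the authors' value table, and miR-34a without scaling, with spike-in scaling and with P10 replicates 3 and 4, at the values given above.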

Other observations

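Outside the fixed lists, 42 of 93 tested miRNAs passed, 23 higher and 19 lower in adult, and the examples here were chosen after their values were seen. miR-203, known from skin epithelium, fell (limma adjusted p = 0.00112, n = 4 per age) to the floor on 3 of 4 adult arrays, so that no size is given. miR-15b fell by 1.12 and its cluster partner miR-16 by 0.33, and both arms of miR-532 fell (miR-532-5p by 1.03, and miR-532-3p to the floor on all 4 adult arrays, so that no size is given). Among those that rose were miR-344a-3p (limma adjusted p = 5.74e-05) and miR-325-5p, both at the floor on 3 of 4 P10 arrays, miR-325-3p (1.76), miR-598-3p (1.42), miR-455 (1.31) and miR-185 (0.89).

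The tests of splits, of hairpin arms and of the miR-132 and miR-212 pair were chosen after the values had been seen. The 35 splits of the 8 arrays into 4 and 4 were each fitted with limma. The real split called 113 miRNAs and the highest of the others 0, so that 1 of 35 reached the real count, the smallest share possible. Every other split mixes the ages, so that an age difference adds to the spread within its groups and lowers its calls. The split test makes chance unlikely for the count of miRNAs but cannot exclude it. For lists, the real split called 5 and others up to 9, and 8 of 35 splits, the real one included, called at least 5. Chance cannot be excluded for the number of lists that camera called at the preset correlation. A split with 9 lists paired P10 replicates 1, 3 and 4 with adult replicate 4.

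As a hypothesis, the arms of a hairpin may follow their shared precursor. Across 35 hairpins with both arms tested, the log2 differences of the arms correlated with a Pearson r of 0.779 (permutation p = 1e-05, the smallest that 100000 permutations can give) and a Spearman rho of 0.616 (permutation p = 7e-05). Without the 2 hairpins farthest from the median r was 0.719. The arms had the same sign in 21 of 35 hairpins, and in 8 of the 8 where both passed. This is a correlation across miRNAs, which are not independent replicates, and shared array effects can add to it.

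miR-132 and miR-212 come from 1 cluster, yet the difference miR-132 minus miR-212 was higher in adult (n = 4 per age, exact two-sided permutation p = 0.0286, the smallest possible). No size is given, since miR-132 was at the floor on P10 replicates 1 and 2, and with normexp miR-132 was 0.55 and not called. miR-494 lay at 3.92 and 3.13 on P10 replicates 1 and 2 and at -1.55 and -0.33 on replicates 3 and 4 (adjusted p = 0.11 between ages, limma).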
